A study of Homo sapiens with 32 samples.

How the data were processed

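The samples were A375 cells, an established human melanoma line, grown at 37 °C in 5% CO2, with total RNA extracted by a column kit, per the labels. The labels list 32 samples in groups of 4: bulk RNA-seq of each of 4 lines labelled TFAP2A knockout (KO1, KO2, KO3 and KO4), single-cell RNA-seq of the KO4 line and of parental cells, and cells with a non-targeting shRNA (shNT) or an shRNA against TFAP2A (shTFAP2A). The titles of the shNT and shTFAP2A samples name single-cell RNA-seq, while their descriptions also name the table of the shRNA comparison, so the kind of library behind that table is not settled here. The labels list no bulk sample of parental cells, and the parental columns of the tables name no sample. The libraries behind those columns are therefore not known here. Separate parental libraries, if any, and the single-cell matrices were not analysed here.

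The authors compared groups with Cuffdiff and deposited 5 tables, each with 1 line per locus for 32185 loci. The submitters' processing notes name Trimmomatic, STAR, Cufflinks and Cuffdiff without versions, the GRCh38 genome, and also BWA, SAMtools 1.3.1, GATK 4.0.5.2 and Cell Ranger 3.1.0, with no role or order. Whether reads were counted by strand is not given in the sources used here. Per the file headers, the authors give each group's level as FPKM, a level scaled by transcript length and by the number of fragments, pooled over the libraries of the group. The score per locus is the authors' deposited test statistic, of the same sign as the fold change. The authors' deposited p-value has a minimum of 5e-05, and their q-value equals a Benjamini-Hochberg adjustment over the loci marked as tested, to within 5.22e-07. The deposited column of log2 fold changes holds cells that a spreadsheet had turned into text, so log2 changes were recomputed here as log2 of the treated over the control FPKM, without a pseudocount. They differed from the finite deposited values by at most 0.00231. The planned design had taken that column as it stood, and this is a departure from it. The parental FPKM of a gene differs between the 4 knockout tables by a nearly constant factor, so levels set side by side across tables come from separate normalizations.

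A gene was called where the authors had tested it and q was at most 0.05. Loci naming several genes (472), loci with a date in place of a symbol (29) and symbols on several lines (4156 lines) were left out, which left 27611 symbols. Genes also needed an FPKM of at least 1 in the higher group. Every gene the authors tested already lay above that, with a lowest level of 1.43 FPKM in the shRNA table. The tables hold no value per library, so no spread between replicates, no paired fit and no permutation of samples could be computed, the depth per library is unknown, and every q is the authors'. An SE printed beside a log2 change is that change divided by the authors' statistic. In each table a statistic of 1.02 to 1.03 best separated called from other genes, at the price of up to 4.71% of genes on the wrong side, so these SEs are larger than the authors' p-values imply, and the factor that would reconcile them is 0.498.

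Counts of genes called with the same sign in all 4 knockout tables were set beside 100 simulated sets of tables that had no effect and shared the control, with a share of 0.5 of the variance given to that control, and beside the product expected of independent lists. Pearson's r and Spearman's rho were computed across genes, which are not independent replicates, so no p-value is given for them. The overlap between knockouts and shRNA was tested with a one-sided Fisher's exact test per direction. A total of 30 gene lists were fixed before the data were examined: AP-2 family, E2F transcription factors and pocket proteins, E2F targets and DNA replication, mitosis and G2/M, PRC2, melanocyte differentiation, a neural crest-like and dedifferentiated melanoma state, mesenchymal and matrix genes, epithelial adhesion and keratins, integrins and melanoma adhesion molecules, p53 targets, CDK inhibitors and cyclin D, MAPK output, interferon response, antigen presentation, NF-kB and inflammatory cytokines, hypoxia and glycolysis, cholesterol biosynthesis, unfolded protein and amino acid response, cancer-testis antigens, HOX genes, axon guidance, immediate early genes, heat shock, mitochondrially encoded genes, ribosomal proteins, replication-dependent histones, markers of lymphoid and myeloid cells, markers of keratinocytes and endothelium, and housekeeping genes. Each list with at least 5 tested members was tested for called members against all tested genes with a one-sided Fisher's exact test, adjusted by Benjamini-Hochberg over lists and directions within a comparison. The median log2 change of each list was placed among 10000 random lists of the same size matched on mean FPKM in 20 bins, and its percentile is given as a description. Medians were taken over members with a finite change, in every line for the knockouts. Some of them therefore rest on fewer members than the tested count printed beside them. No symbol of the mitochondrially encoded list matched (0 members). The grouping, the tests, the lists, the alternatives and the rule for named genes were chosen before the data were examined, except where the closing part says otherwise.

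Named genes were chosen by a rule. It took TFAP2A and the AP-2 family, EZH2 and the E2F genes always. It added the 12 higher and 12 lower genes called in all 4 knockout tables whose weakest table changed most, the 10 higher and 10 lower genes that changed most with shRNA, and up to 10 each way called with 1 sign in all 5 tables. It also took up to 5 each way called with opposite signs in knockouts and with shRNA, up to 6 called with opposite signs between knockout lines, and up to 4 per list. Genes such as ribosomal proteins, histones, MAGE genes and the pseudogene RPL13AP5 share sequence with near-identical copies, and their levels are uncertain. The same holds for overlapping and antisense genes. A few genes that the rule takes are not reported here. Of 178 named genes, 172 matched GENCODE 29 by symbol and overlapping position.

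Alternatives were a q of at most 0.01, a minimum absolute log2 change of 1, FPKM minimums of 1 and 5 and none, q recomputed from the deposited p-values, centring on the median gene, keeping the highest line of a repeated symbol, calls in at least 3 lines, leaving out each knockout line, each line alone, pseudocounts of 1 and 0.1, Spearman's rho and other shares of control variance. A shifted log2 change has no q, so for centring, and for a removal of the trend with transcript length added after seeing the data, genes were called where the shifted change over its SE passed the limit on the statistic. That limit without a shift was therefore added as an alternative of its own. The calling steps were tested on simulated tables with 200 of 8460 genes changed by a fold of 2. They recovered 84.5%, 84.5%, 82% and 85.5% of them for KO1 to KO4 and 96.5% for shRNA, with 1.74%, 3.98%, 5.75%, 3.39% and 2.53% of calls false. The simulated noise was normal, with the SE divided by the limit on the statistic and by 2, and p-values came from that same SE. The share of false calls was thus largely set by the adjustment, and the authors' own test was not run. These values check the steps only and are not error rates of the calls reported below. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.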

Results

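The study asked how the transcriptome of A375 melanoma cells changes with loss of AP-2alpha, the transcription factor that TFAP2A encodes. Its title names E2F, the family of transcription factors that drives S-phase genes, and EZH2, the methyltransferase of the polycomb complex PRC2. The values reported here come from the authors' 5 comparison tables. In 4 of them parental cells were set against a line labelled knockout (KO1 to KO4), and in the fifth shNT cells against shTFAP2A cells. The labels do not say that the samples of a group are separate cultures, so the authors' q-values may measure technical spread only. FPKM in the authors' deposited tables summed to between 1052335 and 1102515 for parental cells, to between 402578 and 458688 for the lines labelled knockout, to 1043916 for shNT and to 1064150 for shTFAP2A. The median log2 change of all tested genes was 0.12, 0.14, 0.09 and 0.10 in KO1 to KO4 and 0.01 with shRNA. Relative to the median gene, log2 changes are lower by these amounts, and no named gene that was called turned sign when they were subtracted. Parental levels printed below are those of the KO1 table unless another table is named.

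TFAP2A mRNA fell with shTFAP2A and went both ways in the lines labelled knockout. The gene (locus XLOC_024865, chromosome 6, 10396677 to 10419564 of GRCh38) is protein-coding, and the locus spans its exons and introns. In the authors' deposited shRNA table it went from 2.96 to 0.848 FPKM, a log2 change of −1.80 (SE 0.462, q = 0.000118). In the authors' deposited KO1 table it fell from 4.04 to 2.33 FPKM (log2 −0.79, SE 0.512, q = 0.0040), while in those of KO2 and KO4 it rose from 3.97 to 7.68 (log2 0.95, SE 0.388, q = 8.24e-05) and from 4.16 to 6.72 (log2 0.69, SE 0.394, q = 0.000781). The change from 4.14 to 3.62 FPKM in the authors' deposited KO3 table was not called (log2 −0.19, q = 0.402). Relative to the median gene the changes were −0.91, 0.82, −0.28 and 0.59 in KO1 to KO4. An edit that disrupts a protein need not lower its mRNA, and the edited position is not given in the sources used here, so these levels leave open whether AP-2alpha was lost, and lines are named by their labels throughout. TFAP2B and TFAP2C, which encode related AP-2 factors, were lower in all 5 tables. In the authors' deposited tables TFAP2C went from 72.8 FPKM in parental cells to between 22.4 and 48.7 in the lines labelled knockout, and from 14.4 to 7.48 with shRNA. TFAP2B went from 41.6 to between 14.5 and 26.9, and from 74.3 to 62.6 with shRNA, in the authors' deposited tables. All 3 tested members of the AP-2 list were thus lower with shRNA and 2 of 3 in all 4 lines labelled knockout, too few for a test. TFAP2D was listed at 0 in all 5 tables.

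**Figure D1:**
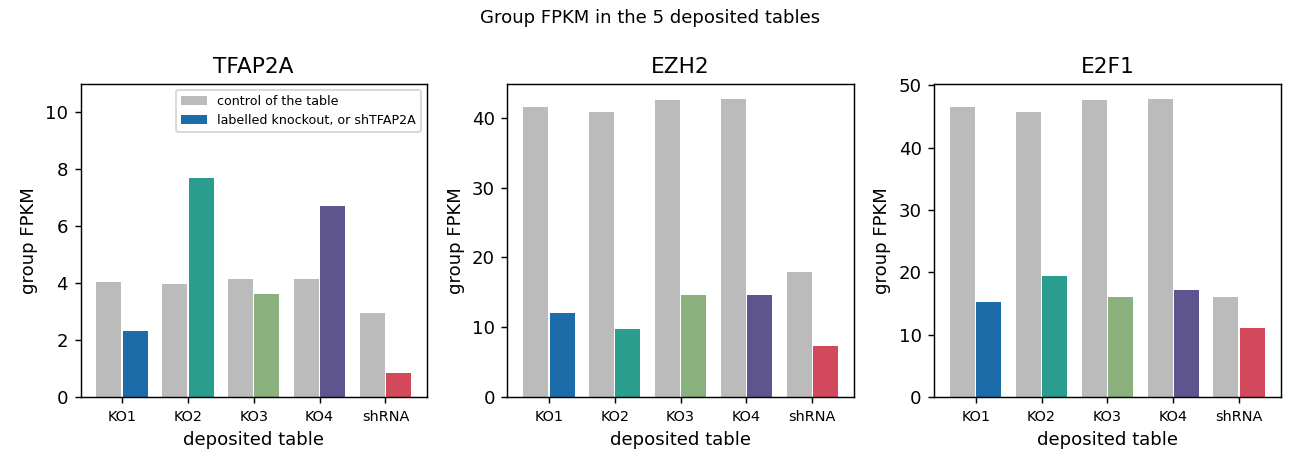
Group FPKM (y axis, linear from 0) of TFAP2A, EZH2 and E2F1 in the 5 deposited tables (x axis), with the control of each table in grey and the line labelled knockout or shTFAP2A in colour; each bar is the authors' single value per group and has no error bar. TFAP2A stood at 0.848 with shTFAP2A but at 7.68 in the line labelled KO2, while EZH2 and E2F1 lay below the control in every table.

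EZH2 and E2F1 were lower in all 5 tables, with every line labelled knockout and with shRNA. EZH2 (locus XLOC_028413, chromosome 7, 148807372 to 148884349 of GRCh38) went from 41.5 FPKM in parental cells to 12.04, 9.85, 14.6 and 14.6 in KO1 to KO4 and from 17.9 to 7.36 with shRNA in the authors' deposited tables. Those are log2 changes of −1.78, −2.05, −1.54 and −1.55 (SE 0.239 to 0.275) and of −1.28 (SE 0.182). E2F1 (locus XLOC_018491, chromosome 20, 33675486 to 33686404), an activator of S-phase genes, fell by 1.60, 1.23, 1.57 and 1.47 on the log2 scale in KO1 to KO4 and by 0.52 with shRNA. In the authors' deposited tables it went from 46.4 FPKM in parental cells to between 15.3 and 19.5 in the lines, and from 16.0 to 11.2 with shRNA. In these separately normalized tables the shNT control stood near the lines for E2F1, and below parental cells for EZH2 (17.9 against 41.5). The falls in the lines are therefore not separated from that difference between the controls. The authors' deposited q for EZH2 and E2F1 was at most 8.63e-05 in the 4 knockout tables and 0.000118 with shRNA. E2F6, a repressor of the family, was also lower in all 5, with log2 changes of −1.55, −2.11, −1.03 and −1.21 in KO1 to KO4 and −0.80 with shRNA. E2F5 and E2F7, which act mainly as repressors, rose in all 4 lines labelled knockout, E2F5 by 3.44 to 3.68 and E2F7 by 1.10 to 1.82, and neither was tested with shRNA. E2F3 rose in KO3 and KO4 (log2 0.77 and 1.00), and E2F4 rose in KO1, KO3 and KO4 (0.72, 1.18 and 0.58) and with shRNA (0.38). E2F2 and E2F8 were called in no knockout table and were not tested with shRNA. Of the 12 tested E2F factors and pocket proteins, 4 were higher and 2 lower in all 4 lines labelled knockout (median log2 0.50). With shRNA 1 of 9 was higher and 5 were lower (median −0.52), or 2 higher when adjusted over the list alone. Neither comparison passed the test (adjusted p of 1 for both directions in the knockouts and, for lower genes with shRNA, of 0.365, Fisher's exact test). PRC2 members did not pass that test either. In the lines labelled knockout 6 of 10 were lower and 2 higher (median −1.04, adjusted p = 0.309 for lower, Fisher's exact test), and with shRNA 6 of 10 were lower and 0 higher (median −0.38, adjusted p = 0.28, Fisher's exact test). PHF19, which guides PRC2 to chromatin, fell by 3.59 to 4.53 in the lines and by 1.16 with shRNA, and RBBP7, a histone-binding subunit, fell by 1.34 to 1.67 and by 1.21.

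Against parental cells, the 4 lines labelled knockout shared very large changes, among them rises of GDF15, SERPINA3 and GPNMB and falls of MDK and FST. GDF15, a stress-induced cytokine, went from 1.25 FPKM to between 427 and 977 in the authors' deposited tables. SERPINA3, a secreted protease inhibitor, went from 23.4 to 7190, 8934, 2675 and 1144 FPKM in KO1 to KO4, and GPNMB, a melanosomal glycoprotein, from 5.44 to between 370 and 429, in the authors' deposited tables. MDK, which encodes the growth factor midkine, went from 461 FPKM to between 0.126 and 0.274, and FST, the activin antagonist follistatin, from 763 to between 0.258 and 0.672, in the authors' deposited tables. Among genes with a finite change in every line, the others with the largest shared rises were CYP27A1 (sterol hydroxylase), GAB2 (signalling adaptor), SPHK1 (sphingosine kinase), GPRC5B, SORL1 (sorting receptor), PDK4 (inhibitor of pyruvate dehydrogenase), GAA (lysosomal glucosidase), SAMD4A and SPSB1, each by at least 5.34 on the log2 scale in every line. The other largest shared falls among such genes were those of LSMEM2, RPL13AP5, LY6K, RPL39 (a ribosomal protein, 12965 to between 36.9 and 42.6 FPKM in the authors' deposited tables), S100A2, FAM166A, PHKG1, MAGEA2, CYP3A5 and HIST2H2BF.

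The authors' test called 79.4%, 80.3%, 78.7% and 79.3% of the tested genes in KO1 to KO4. These were 4547 higher and 4091 lower genes of 10884 in KO1, 4520 and 4065 of 10686 in KO2, 4469 and 4069 of 10855 in KO3, and 4519 and 4156 of 10939 in KO4. The median absolute log2 change of called genes, where finite, was 1.48, 1.53, 1.44 and 1.51. Among 9697 genes tested in all 4 tables, 3220 were higher and 3040 lower in every one. The 4 tables share the parental control, and simulated tables without effect that shared it gave 4.78 and 4.99 with a share of 0.5 of the variance from the control and 26.4 and 27.0 with a share of 0.75, while independent lists would give 272 and 231. Log2 changes correlated between lines across 9435 genes with a mean r of 0.950 (0.924 to 0.968) and rho of 0.953, against a simulated r of 0.487 and 0.739 for these shares. Their covariance was 4.41, against a simulated 3.04 and 4.59. With the SE rescaled by 0.498 the simulated values were 0.754 and 1.14, below the observed one for both shares. The parental libraries could not be split, so the part of the shared control was not measured. At the other end, 385 genes were called with opposite signs in 2 lines.

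The lines labelled knockout also stood apart from parental cells in genes that every cell expresses. Of 44 ribosomal protein genes, 31 were lower and 10 higher in all 4 lines (adjusted p = 5.16e-06 for lower, Fisher's exact test). Their median log2 change was −1.97, yet it lay at percentile 90.8 of random lists matched on level, so that test and percentile point in opposite directions. RPL35 went from 18795 FPKM to between 918 and 1039 while RPS29 went from 66.6 to between 1626 and 2167 in the authors' deposited tables. The SD of log2 changes over the 44 genes was 2.35 to 2.47 in the 4 lines and 0.284 with shRNA, and KO2, KO3 and KO4 differed from KO1 with an SD of 0.222, 0.189 and 0.195. Replication-dependent histones, whose mRNAs lack a poly(A) tail, had 7 of 17 members lower and 0 higher (adjusted p = 0.844, Fisher's exact test). The median of the 14 members with a finite change was −5.89, below every matched random list. HIST1H4C was listed at 4332 FPKM in parental cells and at 0.130 to 0.486 in the lines in the authors' deposited tables, and was called in none of them. With genes called by a limit on the authors' statistic in place of q, 13 histones were lower (adjusted p = 0.00344, Fisher's exact test, with a range of 0.00344 to 1 over its alternatives). Across 13847 loci with an FPKM of at least 1 in a group, parental levels correlated with those of shNT at r = 0.948 and with those of the lines at 0.711 to 0.743, on log2(FPKM + 1) from separately normalized tables, while the lines correlated with each other at 0.932 to 0.965.

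**Figure D2:**
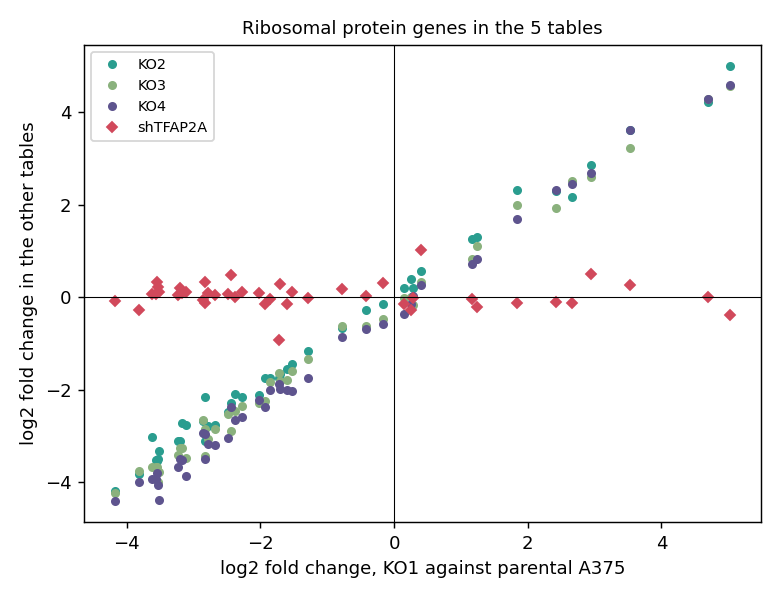
Log2 change of each ribosomal protein gene in KO1 against parental cells (x axis) and in KO2, KO3, KO4 and with shTFAP2A (y axis, one point per gene and table). The lines labelled knockout followed KO1 closely over a range of −4.40 to 5.02, while changes with shTFAP2A had an SD of 0.284.

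Pigment-cell genes rose in the lines labelled knockout. Of 14 tested genes of melanocyte differentiation, 11 were higher and 1 lower in all 4 lines (adjusted p = 0.0158, Fisher's exact test), with a median log2 change of 2.92. MITF, the regulator of the melanocyte lineage, went from 7.13 FPKM to 39.7, 59.3, 49.5 and 96.1 in KO1 to KO4 in the authors' deposited tables. PMEL, a melanosome matrix protein, went from 0.366 to 6.76, 24.6, 35.2 and 1114 FPKM, and MC1R, the melanocortin receptor, from 0.537 to between 3.70 and 12.3, in the authors' deposited tables. Genes of hypoxia and glycolysis rose too, with 16 of 25 higher and 4 lower (median 1.61, adjusted p = 0.0249, Fisher's exact test). PFKL, a phosphofructokinase, rose by 3.27 to 3.76, ENO2, an enolase, by 1.94 to 3.64, and ADM, the vasodilator adrenomedullin, by 3.38 to 4.19. Integrins and adhesion molecules were higher for 11 of 16 members and lower for 2 (median 1.15, adjusted p = 0.0465, Fisher's exact test), among them ICAM1 (4.58 to 5.66), ITGAV (4.22 to 4.52), MCAM (2.95 to 4.34) and ITGB3 (2.71 to 4.25). In the same tables the 44 ribosomal protein genes had an SD of 2.35 to 2.47. Without KO2 neither hypoxia genes (adjusted p = 0.0550, Fisher's exact test, with a range of 0.00424 to 0.0550 over its alternatives) nor integrins (0.0837, range 0.0154 to 0.758) passed. Integrins also failed without KO1 (0.0557), without KO4 (0.0590), with a limit on the statistic in place of q (0.0542), with a trend with transcript length removed (0.180) and with a minimum absolute log2 change of 1 (0.758, Fisher's exact test). For all lists, counts adjusted over the list alone were equal to those over all genes in the knockout comparison.

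Other lists of growth and stress genes held strong single changes without passing the test in the lines labelled knockout. Of 22 p53 targets, 12 were higher and 2 lower (median 1.498, adjusted p = 0.209, Fisher's exact test), with CCNG1 up by 3.06 to 4.45 and DDB2, a DNA repair factor, by 3.26 to 3.77. With a minimum absolute log2 change of 1 that list did pass (adjusted p = 0.0135, Fisher's exact test, range over its alternatives 0.0135 to 0.478). Cholesterol synthesis genes were higher for 12 of 20 and lower for 1 (median 1.24, adjusted p = 0.11, Fisher's exact test), and they passed without KO4 (0.0180) or when 3 lines sufficed (0.0386), the range over alternatives being 0.0180 to 1. Of 46 E2F targets and DNA replication genes, 15 were higher and 19 lower (median −0.25, adjusted p = 0.474 for lower, Fisher's exact test). UHRF1, a partner of DNA methylation, fell by 2.64 to 4.16 and GINS2, of the replicative helicase, by 2.62 to 3.49, while CHAF1B, a histone chaperone, rose by 2.53 to 2.87. Of 33 mitotic genes 9 were higher and 10 lower (median −0.20), and AURKB, a mitotic kinase, fell by 1.92 to 3.16. CDK inhibitors and cyclin D genes were lower for 5 of 7 and higher for 1 (median −1.33, adjusted p = 0.209 for lower, Fisher's exact test). Within them CCND1 (cyclin D1) went from 232 FPKM to between 19.1 and 44.2, and CDKN1A (p21) from 10.2 to between 64.8 and 150, in the authors' deposited tables. The unfolded protein and amino acid response had 10 of 21 higher and 3 lower (median 0.76), with ATF4, its central factor, up by 2.52 to 3.74. Mesenchymal and matrix genes had 9 of 26 higher and 4 lower (median 0.49), SNAI2, a repressor of epithelial genes, rising by 5.30 to 5.84, while PLAUR, the urokinase receptor, fell by 4.55 to 6.54. Genes of the dedifferentiated melanoma state had 2 of 12 higher and 2 lower (median −1.61, percentile 0.57 of matched lists). AXL, a receptor kinase of that state, stood at 83.8 FPKM in parental cells and at 0.0185 to 0.199 in the lines in the authors' deposited tables, but was called in KO1, KO2 and KO3 only. MAPK output had 7 of 16 higher and 4 lower (median 0.16), and FOSL1, a partner of JUN in AP-1, fell by 3.29 to 3.95. Immediate early genes had 4 of 13 higher and 3 lower (median 0.48), with MYC up by 3.51 to 4.00, while JUN fell by 3.61 to 4.40. Heat shock genes had 7 of 10 lower and 2 higher (median −0.73, adjusted p = 0.11 for lower, Fisher's exact test), and housekeeping genes 5 of 13 lower and 4 higher (median −0.15). GAPDH went from 1020 to between 3813 and 5635 FPKM in the authors' deposited tables. Of the epithelial list 1 of 2 tested members was higher, DSP, a desmosomal protein, by 2.22 to 3.29.

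**Figure D3:**
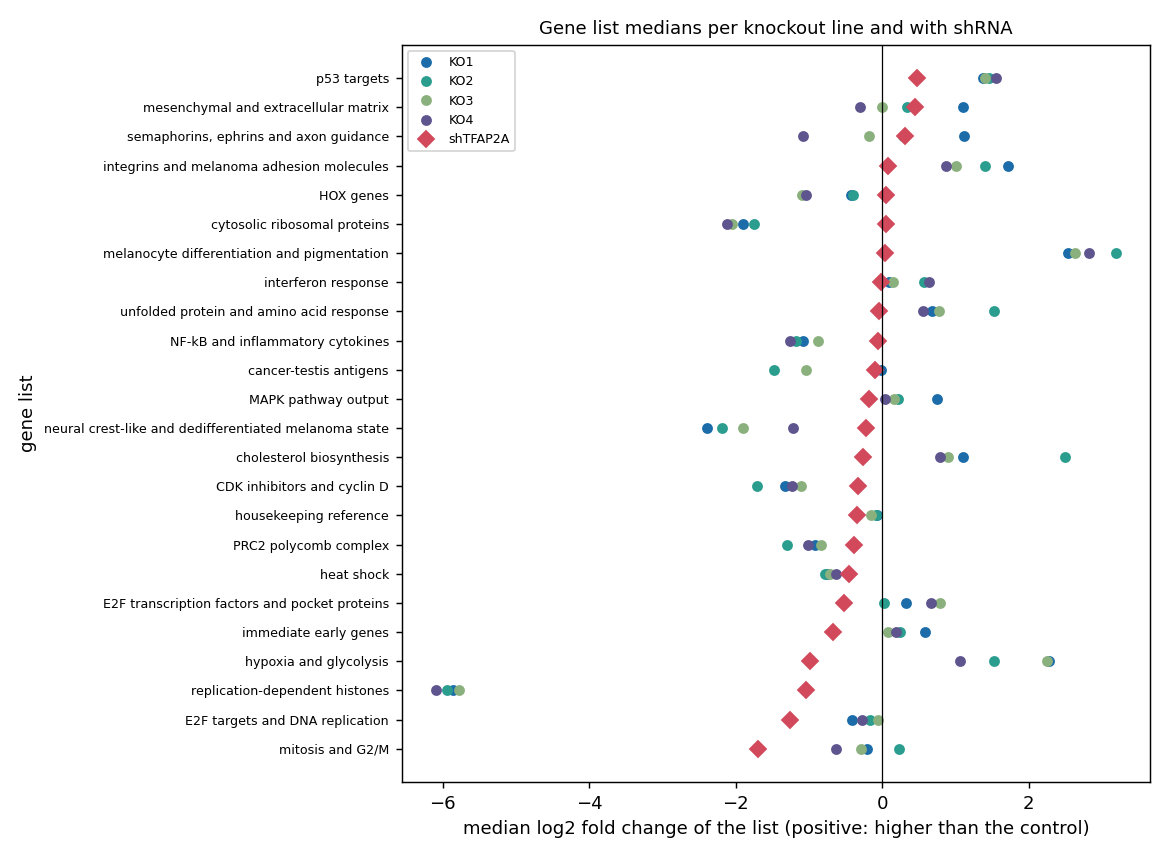
Median log2 change (x axis, linear) of each tested gene list (y axis) in KO1 to KO4 against parental cells (circles) and with shTFAP2A against shNT (diamonds). With shTFAP2A the mitosis list stood lowest at −1.70, and in the lines labelled knockout the histone list stood lowest, at −5.89 for the mean of the lines.

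With shTFAP2A, genes of the cell cycle and of glycolysis fell together, and changes were smaller than in the lines labelled knockout. All 33 tested mitotic genes were lower (median log2 −1.70, adjusted p = 3.64e-15, Fisher's exact test), and so were all 38 E2F targets and DNA replication genes (median −1.26, adjusted p = 2.86e-17, Fisher's exact test). CCNB1, the mitotic cyclin B1, went from 174 to 45.7 FPKM and RRM2, a ribonucleotide reductase subunit, from 39.5 to 9.37 in the authors' deposited table. The log2 change was −1.62 for AURKB, −1.70 for MAD2L1 (spindle checkpoint), −1.78 for CDC25C, −1.59 for GINS2 and −1.35 for UHRF1. Of 23 hypoxia and glycolysis genes 20 were lower and 0 higher (median −0.99, adjusted p = 2.42e-06, Fisher's exact test), or 21 lower when adjusted over the list alone, and ENO2 fell by 1.07.

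Among genes with a finite change, the largest single rise with shTFAP2A was that of TCN1, a vitamin B12 carrier, from 1.35 to 56.2 FPKM in the authors' deposited table. TTR, the thyroid hormone carrier transthyretin, went from 2.04 to 22.9 and PDLIM2, a cytoskeletal adaptor, from 0.775 to 8.72 FPKM in the authors' deposited table. MRO, PPP1R3F, LOC102724895, DPH6-AS1, FAM71F1, RP4-655J12.4 and LOC146481 completed the 10 largest rises, each by at least 2.96. The largest falls were those of CA9, the hypoxia-regulated carbonic anhydrase IX (log2 −3.46), and PSMC3IP, a recombination factor (−3.37), from 2.43 to 0.221 and from 14.0 to 1.35 FPKM in the authors' deposited table. RMRP (RNA of an endoribonuclease), BEND5, TMSB15A, SYCE2, SPC24 (kinetochore), NMU (neuromedin U), HIST1H2AB and KRT81 (hair keratin) followed, each falling by at least 2.31. The authors' test called 3336 higher and 3386 lower of 10227 tested genes (65.7%), with a median absolute log2 change, where finite, of 0.48. Of those with a finite change, 979 changed at least 2-fold, against 5694 to 5918 in the knockout tables.

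Further lists moved with shTFAP2A by smaller amounts. Mesenchymal and matrix genes rose, with 17 of 25 higher and 6 lower (median 0.45, adjusted p = 0.00361, Fisher's exact test), among them TGFBI (0.97), the matrix protease MMP2 (0.92) and PLAUR (0.53), while SNAI2 fell by 0.48. Of 19 p53 targets 13 were higher and 3 lower (median 0.47, adjusted p = 0.0141, Fisher's exact test), CCNG1 by 0.47 and CDKN1A from 3.28 to 7.62 FPKM in the authors' deposited table. Immediate early genes fell, with 11 of 15 lower and 2 higher (median −0.67, adjusted p = 0.0141, Fisher's exact test), including JUN (−2.16), FOSB (−0.93), MYC (−0.78) and EGR2 (−0.60). Of 9 heat shock genes 7 were lower and 1 higher (median −0.46, adjusted p = 0.0462, Fisher's exact test), among them HSPH1 (−0.57) and HSP90AA1 (−0.56). Housekeeping genes were lower for 9 of 13 and higher for 0 (median −0.34, adjusted p = 0.0462, Fisher's exact test), among them TFRC, the transferrin receptor (−0.87), and GAPDH (−0.36). Some lists share members: GAPDH and PGK1 are also in the hypoxia and glycolysis list, and RPLP0 is also in the ribosomal list. Of 44 ribosomal protein genes 23 were higher and 12 lower (median 0.05, adjusted p = 0.0362 for higher, Fisher's exact test). Each of these lists lost its call with a minimum absolute log2 change of 1, and all but the mesenchymal list with FPKM of at least 5. Over the alternatives the adjusted p of Fisher's exact test ranged from 0.000413 to 0.848 for mesenchymal genes, 0.00264 to 0.111 for p53 targets, 0.00385 to 0.216 for immediate early genes, 0.0399 to 0.985 for heat shock, 0.0186 to 0.568 for housekeeping genes and 0.0103 to 1 for ribosomal proteins.

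The remaining lists did not pass the test with shTFAP2A. Melanocyte genes had 2 of 9 higher and 3 lower (median 0.03), or 3 higher when adjusted over the list alone, with MITF up by 0.20 while GPNMB fell by 0.87. Genes of the dedifferentiated state had 4 of 11 higher and 7 lower (median −0.22), and integrins 6 of 16 higher and 3 lower (median 0.08), or 2 lower when adjusted over the list alone. CDK inhibitors and cyclin D genes had 2 of 8 higher and 5 lower (median −0.33), CCND1 going from 163 to 50.0 FPKM in the authors' deposited table. MAPK output had 6 of 18 higher and 9 lower (median −0.18), cholesterol synthesis 5 of 18 higher and 9 lower (median −0.26), and the unfolded protein response 9 of 19 each way (median −0.05), and ATF4 fell by 1.17. Replication-dependent histones had 10 of 18 lower and 2 higher (median −1.04, adjusted p = 0.186 for lower, Fisher's exact test), and passed with a minimum absolute log2 change of 1 (2.26e-05) or with a limit on the statistic in place of q (0.0248), the range over alternatives being 2.26e-05 to 0.186. HIST1H4C went from 7658 to 2796 FPKM in the authors' deposited table. Of 4 tested epithelial genes 3 were higher and 0 lower, or 4 higher when adjusted over the list alone, KRT8 by 1.87.

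Some genes moved the same way in all 5 tables, among them PDLIM2, which was higher, and PSMC3IP, which was lower. The genes named here had a finite change in every table, which leaves out genes listed at 0 in a group, such as LOC146481. PDLIM2 rose by 2.48 to 2.98 in the lines labelled knockout and by 3.49 with shRNA, and EEPD1, KCNE4 (channel subunit), NOV (matricellular protein), CPM (carboxypeptidase), PTPRZ1 (receptor phosphatase), KCNS3 (channel subunit), POLB (repair polymerase), PI15 and PBXIP1 followed. PSMC3IP went from 64.5 FPKM in parental cells to between 7.50 and 12.1 in the lines in the authors' deposited tables and fell by 3.37 on the log2 scale with shRNA. JUN went from 65.5 FPKM to between 3.17 and 5.52 and from 55.6 to 12.4 in the authors' deposited tables. RRM2, NFIB, CCNB1, DCTN3, ENOSF1, KIAA0101 (PCNA-associated factor) and TMTC3 were among the other strongest shared falls, each by at least 1.77 with shRNA. Among 8606 genes tested in all 5 tables, 1311 were lower in all 4 lines and with shRNA, against 1066 from independent lists (ratio 1.23, one-sided Fisher's exact test, p = 7.03e-31), and 865 were higher, against 793 (ratio 1.09, one-sided Fisher's exact test, p = 0.000143). For KO2 alone the ratio for higher genes was 1.02 (Fisher's exact test, p = 0.122). With a minimum absolute log2 change of 1 the ratio was 1.15 for lower genes (Fisher's exact test, p = 0.0434) and 1.69 for higher genes (Fisher's exact test, p = 2.13e-06). With FPKM of at least 5 it was 1.11 for lower and 1.19 for higher genes. Genes are not independent replicates, so the p-values of these overlaps overstate the evidence, and the ratios are given as descriptions. Of genes higher in the lines, 647 were lower with shRNA (882 from independent lists), and of genes lower in the lines, 993 were higher with shRNA (959 from independent lists).

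Across 8460 genes the mean log2 change of the lines labelled knockout correlated only weakly with that of shTFAP2A, with r = 0.119 and rho = 0.112. The r was 0.118, 0.0919, 0.108 and 0.147 for KO1 to KO4 alone. Several genes moved in opposite directions. MT2A, a metallothionein, rose by 2.21 to 3.95 in the lines and fell by 2.17 with shRNA, and SERPINA3 went from 34.1 to 8.55 FPKM with shRNA in the authors' deposited table. SLIRP (mitochondrial RNA binding), SPRY1 (a MAPK inhibitor) and MYH10 (nonmuscle myosin) were also higher in the lines and lower with shRNA. HIST1H2BK, MMP24-AS1, FAM3C and CCDC90B were lower in the lines and higher with shRNA. TFAP2A mRNA itself fell with shRNA but rose in KO2 and KO4, so these directions are those of the lines labelled knockout, not of a shown loss of TFAP2A.

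The 4 lines labelled knockout differed from each other in matrix, cholesterol and mitotic genes. EMILIN1, of elastic fibres, went from 7.28 FPKM to 155, 114, 23.2 and 0.721 in KO1 to KO4, and NNMT, a methyltransferase, from 8.59 to 21.5, 30.3, 0.341 and 0.461, in the authors' deposited tables. PXDN, a peroxidase of the matrix, was lower in KO2 (log2 −7.67) and higher in KO4 (2.57). SEMA3A, a guidance cue, was higher in KO1 (2.40) and lower in KO4 (−2.30), TMSB4X lower in KO1 (−3.22) and higher in KO4 (2.37), and MAGEA1 higher in KO1 (1.10) and KO4 (2.06) and lower in KO3 (−4.27). All 20 tested cholesterol synthesis genes stood highest in KO2, with a median of 1.45 above the mean of the other lines, above every matched random list. STARD4, a sterol transporter, was at 4.78, 14.7, 2.72 and 2.53 FPKM in KO1 to KO4 against 0.434 in parental cells in the authors' deposited tables. In KO4 the 20 cholesterol genes were below the other lines by a median log2 of −0.76. Of 33 mitotic genes, 31 stood highest in KO2 (median 0.64) and 25 lowest in KO4 (median −0.58). Of 25 mesenchymal and matrix genes, 20 stood highest in KO1 (median 0.91) and the median in KO4 was −0.55. Of 21 unfolded protein genes 15 stood highest in KO2 (median 0.70), and of 25 hypoxia and glycolysis genes 18 stood lowest in KO4 (median −0.56). These differences set levels of separately normalized tables side by side, and no test across libraries was possible.

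**Figure D4:**
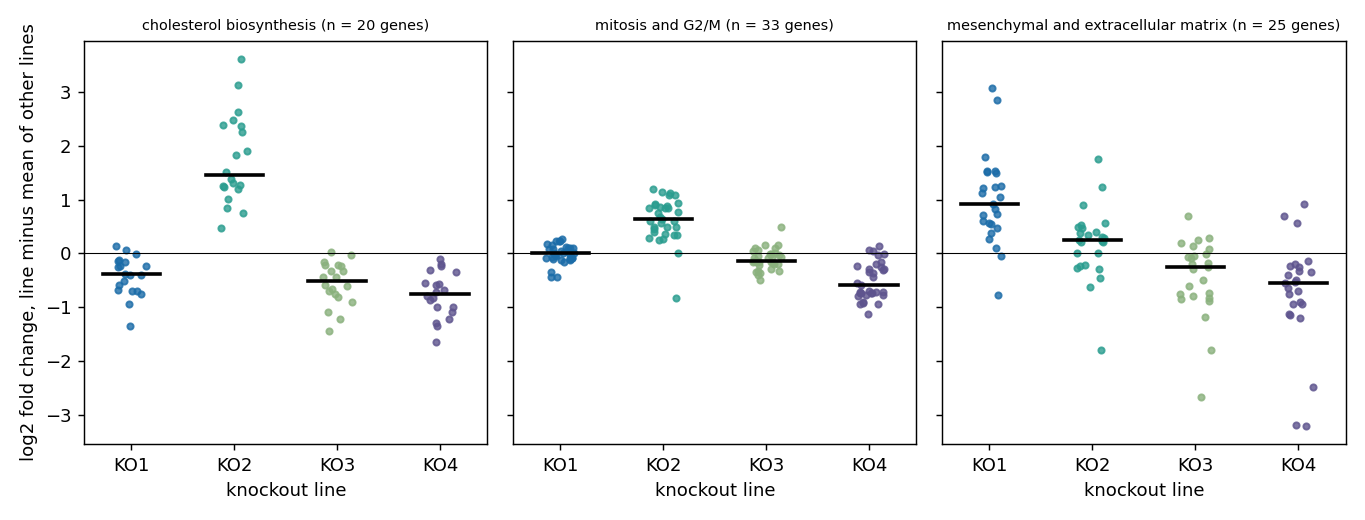
Log2 change of each gene in a line labelled knockout minus the mean of the other lines (y axis, linear) for KO1 to KO4 (x axis) in 3 gene lists, 1 point per gene and a black bar at the median. All 20 cholesterol genes lay above 0 in KO2, and 31 of 33 mitotic genes stood highest there.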

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

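The tests of ribosomal spread, of profile similarity, of scaling, of growth, of cell-cycle genes shared with the lines and of differences between the lines and shRNA were chosen only after the results were seen, as were both removals of a trend with transcript length, whose expected outcomes were written down before their values were known.

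The lines labelled knockout shared large changes against parental A375, with a mean r of 0.950 between lines. A candidate explanation is that the parental libraries were of another kind, or were quantified in another way. The tables hold what it needs: ribosomal protein genes had an SD of 2.40 on the log2 scale in these tables against 0.284 with shTFAP2A. Between the controls shNT and parental, from separately normalized tables, that SD was 1.06. The parental profile was closer to shNT (r = 0.948) and to shTFAP2A (r = 0.921) than to any line (0.711 to 0.743). Any cause that sets the lines apart would give this order, so the profiles do not tell a library difference from a change in the lines. A trend with transcript length as the whole cause is argued against, since a quadratic trend took up 7.70% to 10.7% of the variance of log2 changes in these tables. The r between lines was 0.947 after its removal, but the shared control alone keeps r up, at 0.487 and 0.739 in simulated tables without effect. Loss of TFAP2A cannot be told apart from a difference between libraries, because every line labelled knockout was set against the same parental libraries, and the r of 0.119 with the shRNA table cannot decide. The rises in melanocyte, hypoxia and adhesion genes in these lines may therefore hold a part from the libraries. The same holds for the falls of EZH2, E2F1 and TFAP2C in these lines.

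All 71 E2F targets and mitotic genes tested in all 5 tables fell with shTFAP2A. The median log2 change of 9571 tested genes outside both cell-cycle lists was 0.0107. That argues against a uniform shift of the listed levels between shNT and shTFAP2A as the source of these falls. FPKM is scaled by the number of fragments, so a difference in total RNA per cell cannot be seen in this median. A difference in growth between cultures, without a part for TFAP2A, stays open: E2F targets differed by −1.51 between the controls shNT and parental, in separately normalized tables where all genes had a median of −0.40, against −1.26 between shTFAP2A and shNT. Mitotic genes were also lower in both comparisons, but by less between the controls (−1.44) than between shTFAP2A and shNT (−1.70). Growth rates are not given in the sources used here. Loss of TFAP2A also stays open, as 29 of these 71 genes were lower in all 4 lines and 16 were higher. Among all 8606 genes tested in all 5 tables, 2991 were lower in all 4 lines and 2474 were higher. With the parental libraries in doubt the count of 29 cannot be told apart from a library effect, and the growth of a culture might itself follow TFAP2A.

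Cholesterol synthesis genes were higher in KO2 than in the other lines labelled knockout. Parental levels in the other knockout tables exceeded those in the KO2 table by at most 0.0672 on the log2 scale for the median gene. That value covers the parental columns only and cannot decide on the scale of the KO2 levels. The median log2 change of all tested genes was 0.14 in KO2 and 0.09 to 0.12 in the other lines. That argues against a uniform shift of the KO2 levels as the source of the difference. FPKM is scaled by the number of fragments, so a difference in total RNA per cell cannot be seen in these medians. The cholesterol genes stood higher in KO2 by a median of 1.45. A trend with transcript length is argued against, since the median difference was 1.43 after its removal. No biological explanation was tested, because the labels give nothing but the line number, and a difference between clones or in culture conditions may be among those that stay open.

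Several genes changed in opposite directions in the lines labelled knockout and with shTFAP2A. They were picked because they were called with opposite signs, so no separate test of their differences is given. The mean log2 change of the lines minus that with shRNA was 5.55 for MT2A, 9.31 for SERPINA3, 3.97 for SLIRP, 4.19 for SPRY1 and 3.34 for MYH10. It was −5.70 for HIST1H2BK, −3.83 for MMP24-AS1, −4.48 for FAM3C and −3.71 for CCDC90B. Gene lists were compared by an exact McNemar test of members called in all 4 lines against members called with shRNA, adjusted over 48 tests. A call in all 4 lines is harder to reach than a call in the shRNA table. That alone can lower the counts for the lines. Members of a list are not independent, so the p-values of this test overstate the evidence and are given as descriptions. With the parental libraries in doubt, the list differences below cannot be told apart from a library effect. E2F targets were lower for 19 of 38 members in the lines and 38 with shRNA (adjusted p = 9.16e-05, exact test). Mitotic genes were lower for 10 of 33 in the lines and 33 with shRNA (adjusted p = 1.14e-05, exact test) and higher for 9 and 0 (0.0313). Hypoxia and glycolysis genes were higher for 13 of 22 in the lines and 0 with shRNA (adjusted p = 0.00293, exact test) and lower for 4 and 19 (0.000977). Ribosomal protein genes were lower for 31 of 44 in the lines and 12 with shRNA (adjusted p = 0.00524, exact test).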

How the results depend on the processing

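The removal of a trend with transcript length, the rescaling of the SE and the limit on the statistic in place of q were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the tables hold no value per library, and for the same reason no replicate could be left out and no other split of the samples counted. A minimum FPKM of 1 and no minimum moved nothing, since every tested gene already lay above it, and neither did q recomputed from the deposited p-values, which equals the deposited q to within 5.22e-07, so these say nothing about stability. Of 236 values of summary results under an alternative, 217 kept their direction and side of the threshold, or stayed within the spread or a factor of 1.5 for a count. That tally includes the settings just named, and centring for r, none of which could move a value, so it overstates stability.

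With a minimum absolute log2 change of 1, shRNA calls dropped to 441 higher and 542 lower genes, genes lower in all 4 lines labelled knockout to 2008, and lists higher with shRNA to 0, since that minimum leaves out every smaller change. With FPKM of at least 5, 1 list stayed higher and 3 lower with shRNA, with fewer genes tested, and r between knockouts and shRNA was 0.0893. Centred on the median gene, 2 lists were lower in the lines, histones joining ribosomal proteins (13 members, adjusted p = 0.00782, Fisher's exact test). The limit on the statistic without any centring gave 2 lists as well, with 13 histones (0.00344), so this call came from the limit and not from centring. Leaving out each line in turn gave 1 to 3 lists higher in the lines, the lowest without KO2, where the cause was not tested. For KO2 alone the overlap of higher genes with shRNA had a ratio of 1.02 (Fisher's exact test, p = 0.122) and r was 0.0919, and for KO4 alone r was 0.147; the cause was not tested. The covariance between lines beyond the simulated one was 1.37 with a share of 0.5 of the variance from the control, 2.90 with 0.25, and −0.18 with 0.75, where its sign reversed because the simulated covariance grows with that share. With the SE rescaled, as the authors' p-values imply, it was 3.65, 4.03 and 3.27 for these shares, and the sign did not reverse. A pseudocount of 1 moved the TFAP2A change with shRNA to −1.10, as it must for a gene near 1 FPKM, and moved 91 changes of named genes by more than their SE, against 254 within it. With centring 328 changes of named genes stayed on their side of the threshold, 9 gained and 8 lost a call, and none that was called turned; the limit on the statistic was not separated from centring there.

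Over the alternatives of each list, the adjusted p of Fisher's exact test ranged from 0.000958 to 0.0461 for melanocyte genes, from 3.63e-08 to 0.0136 for lower ribosomal proteins, and from 0.00424 to 0.0550 for hypoxia genes, in the lines labelled knockout. Integrins passed in 8 of 14 alternatives. With shRNA it was at most 3.89e-11 for E2F targets, 5.09e-11 for mitotic genes and 2.86e-06 for hypoxia genes. Of 9 alternatives with shRNA, mesenchymal genes passed in 8, p53 targets, immediate early genes and ribosomal proteins in 7, housekeeping genes in 6 and heat shock in 4. The alternatives counted here, of 14 and of 9, include no FPKM minimum and recomputed q, which could move nothing. Heat shock and housekeeping genes also failed when the highest entry of a repeated symbol was used (0.178 and 0.110), and heat shock with q of at most 0.01 (0.0929) and with the length trend removed (0.125). With the length trend removed, 2852 genes were higher in all 4 lines, of which 2618 were among the 3360 called by the same limit on the statistic without that removal. The lower genes were 3505, of which 2828 were among the 3106 called so. Depth per library is unknown, and 308 to 339 tested genes per knockout table had a group listed at 0 and therefore no finite change.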

Other observations

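All gene groups in this part were fixed before the data were examined; the slopes with transcript length and the levels set across tables were computed only after the results were seen. Of the antigen presentation list, 3 genes were tested in all knockout tables: CD74, CIITA and PSMB10. CD74, the invariant chain of HLA class II, was listed at 2181 FPKM in parental cells and at 55.5, 0.0867, 0.0333 and 0.0590 in KO1 to KO4 in the authors' deposited tables, and CIITA, a regulator of HLA class II genes, fell by 5.42 to 8.09. PSMB10, an immunoproteasome subunit, fell by 1.71 to 1.89, so all 3 tested members of the list were lower, too few for a test. With shTFAP2A, 1 of 3 was higher and 1 lower, CD74 by −0.03 and PSMB10 by 0.37. Interferon response genes had 5 of 15 higher and 3 lower in the lines (median log2 −0.10) and 3 of 16 higher and 5 lower with shRNA (median −0.02). IFI35 rose by 2.98 to 4.29 in the lines and by 1.03 with shRNA, OAS1, an RNA sensor, fell by 1.60 to 3.21 in the lines, and MX2, an antiviral GTPase, was lower in KO1 (−7.29) and higher in KO2, KO3 and KO4 (0.92, 1.24 and 1.43). NF-kB and cytokine genes had 3 of 9 higher and 4 lower in the lines (median −1.12), LIF rising by 4.94 to 6.02, and 2 of 12 higher and 4 lower with shRNA (median −0.06), and CXCL2 fell by 1.67.

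HOX and axon guidance genes did not pass the test in either comparison. Of 20 HOX genes 9 were lower and 2 higher in the lines (median −0.90, adjusted p = 0.566 for lower, Fisher's exact test), and HOXC9 fell by 3.63 to 3.81 while HOXD13 rose by 2.25 to 2.66. With shRNA 4 of 21 were higher and 7 lower (median 0.06). Of 18 genes of axon guidance 6 were higher and 4 lower in the lines (median 0.09), and NRP1, a semaphorin receptor, fell by 5.86 to 7.60, EFNB2, an ephrin, fell by 3.49 to 6.08, and PLXNA1, a plexin, rose by 3.08 to 4.28. With shRNA 9 of 17 were higher and 6 lower (median 0.31, adjusted p = 0.264 for higher, Fisher's exact test), EFNB2 by 0.93 and NRP1 by 0.55. Cancer-testis antigens had 6 of 14 lower and 2 higher in the lines (median −1.18) and 6 of 12 lower and 2 higher with shRNA (median −0.10). CTAG2 rose by 2.92 to 3.34 in the lines and CSAG1 fell by 2.94 to 3.21.

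Of the markers of lymphoid and myeloid cells, CD68, a lysosomal glycoprotein, was the 1 tested in all knockout tables and was higher in all 4 lines (0.99 to 2.52), and both tested with shRNA were higher, LYZ (lysozyme) from 2.93 to 17.7 and CD68 from 1.65 to 3.80 FPKM in the authors' deposited table. Of the keratinocyte and endothelial markers 1 of 2 tested was lower in the lines, KRT10, from 374 FPKM to between 5.75 and 8.15 in the authors' deposited tables, and with shRNA 1 of 2 was higher, again KRT10 (0.64). The log2 change rose with log2 transcript length by 0.587, 0.597, 0.645 and 0.713 in KO1 to KO4 and by 0.0253 with shRNA, and in genes with a single coding transcript by 0.808 to 0.930 and 0.0609. Between the controls shNT and parental, from separately normalized tables, that slope was −0.0209.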
